A study of Mus musculus with 35 samples.

How the data were processed

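RNA from quadriceps muscle of 2-month-old female mice was measured on 35 arrays, 1 per sample, in 4 classes and 2 experiments. Per the labels, muscles were dissected and snap-frozen, total RNA was extracted with TRIzol, and biotin-labelled sense-strand targets were made with a whole-transcript assay. Each class had 3 arrays in experiment 1, and in experiment 2 it had 5 arrays, or 8 for the Mstn-null class. The labels call the samples of a group biological replicates from separate mice, so p-values here measure the spread between animals. The number of arrays limits the precision of every value.

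The deposited values are log2 expression values, made by the authors with RMA, per the submitters' processing notes, which also name limma 3.4.4 and R 2.11.1 without a role. Base 2 was taken from the range of the values, which reached 14.7. Whether both experiments were normalized together is not given in the sources used here. Array medians near 4.4 in experiment 1 and near 6.1 in experiment 2 show that levels are not comparable between them, so the main fit held the experiment as a term and levels are given within an experiment. The genome build behind the probe design is not given in the sources used here, and signal over background was not analysed here.

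The deposited table held 35556 rows. The annotation paired 21789 rows with exactly 1 gene symbol, 1621 with several and 12146 with none. Of the first, 21698 matched a gene in the RefSeq table of the mouse assembly GRCm38.p6 by gene number, and 0 symbols needed an update. Rows with several symbols or none were left out of the main comparisons. For 999 genes with more than 1 row, the row with the highest mean over all arrays was used, which left 19938 genes. No filter on dim genes was applied.

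Comparisons were made with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with default settings, two-sided) in a single fit of all 35 arrays with class and experiment as terms. Benjamini-Hochberg adjusted p-values under 0.05 over all genes were called. The comparisons were Mstn-null against control, 1 dose against control, 4 doses against control, 4 doses against 1 dose, and each dose against Mstn-null. A fit of 8 group means tested, for each class, whether its change against control differed between the experiments. Changes are log2 differences with their standard errors from the fit.

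For gene sets, 30 lists were fixed in advance from general knowledge: slow and fast fibre contractile genes, oxidative phosphorylation, tricarboxylic acid cycle, fatty acid uptake and oxidation, glycolysis and glycogen, atrophy with autophagy and FoxO genes, the IGF, AKT and mTOR pathway, TGF-beta and activin signalling, BMP targets, satellite cell and myogenic genes, denervation and neuromuscular junction genes, cell cycle, extracellular matrix, cytoplasmic ribosomal proteins, ATF4 and serine synthesis, polyamine metabolism, circadian clock, immediate early genes and interferon response, as well as markers of macrophages and myeloid cells, lymphocytes, endothelium, smooth muscle, Schwann cells, tendon, adipocytes, fibro-adipogenic progenitors, erythroid cells and sex. Each was tested with limma's camera at a preset correlation of 0.01, Benjamini-Hochberg adjusted over the lists within a comparison, with camera at an estimated correlation and fry beside it. For each list the genes past the threshold over all genes and adjusted over the list alone were counted.

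The genes named in the text follow a rule set in advance. It takes Mstn, then for each comparison against control the 10 largest rises and 10 largest falls among genes past the threshold with the same sign of change in both experiments, for the other comparisons 5 and 5, and for each described list up to 4 members with the smallest p. Symbols that are only clone or model numbers, olfactory and vomeronasal receptors and small RNA genes were counted but not named. Igf2 and Mss51 are also given in comparisons where the rule did not choose them, for contrast. Other exceptions are stated where they occur.

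Before use, the fits were tested on simulated data with 100 genes changed by a log2 value of 0.5 and 100 by 1, among 19938 genes with the spread of these arrays. For Mstn-null against control 91% and 99% of them were called, for 1 dose 88% and 100%, for 4 doses 87% and 99%, for 4 doses against 1 dose 86% and 98%, for 4 doses against Mstn-null 91% and 99%, and for 1 dose against Mstn-null 91% and 100%. The tests between experiments found 15% and 83% for Mstn-null, 20% and 78% for 1 dose, and 13% and 80% for 4 doses. In simulated data for each of the 3 comparisons against control, camera called the shifted list and 0 of the 29 others. This does not show that camera's preset correlation suits the real lists. Their estimated correlation could be far higher, at 0.554 for oxidative phosphorylation and 0.685 for slow fibre genes.

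Within groups, arrays correlated across genes between 0.954 and 0.996, and no array was a copy of another, the smallest root mean square difference between arrays of a group being 0.169. Likeness of profiles was described by correlations across genes, beside 50 simulated sets of unchanged groups against the same controls and the mean over 20 divisions of the controls. Tests of single measures between groups were exact permutation tests within experiments, two-sided, and correlations across arrays used 100000 permutations.

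Alternatives were planned before the data were examined: no experiment term, each experiment alone, the replicate number as a block, arrays centred on their medians, quantile normalization over all 35 arrays, genes in the lowest tertile of mean value left out, every row tested, eBayes with trend and robust settings, array weights, a fit of only the classes compared, an adjusted p of 0.01, a change of at least 0.5 on the log2 scale, and each array left out in turn. Added after the data were seen were each array's interquartile range, centred within its experiment, as a covariate, and the removal of 6 arrays with an interquartile range under 2.3. For each comparison 100 splits of the same arrays within experiments, the real one included, were refitted, and for the tests between experiments 100 reassignments of arrays to experiments within a class.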

Results

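The data were gene expression profiles of quadriceps muscle from 2-month-old female mice, measured on 35 arrays, 1 array per sample. Mice fell into 4 classes: controls, Mstn-null mice, and mice that had received 1 dose or 4 doses of ActRIIB-Fc, a soluble form of the activin type IIB receptor that binds myostatin and related ligands. Mstn encodes myostatin, a secreted inhibitor of muscle growth. Each class was studied in a first experiment with 3 arrays per class and in a follow-up experiment with 5 arrays per class, or 8 for the Mstn-null class. The median log2 value per array lay between 4.39 and 4.52 in experiment 1 and between 6.06 and 6.27 in experiment 2, so levels were compared only within an experiment. The comparisons asked which genes change in muscle without myostatin, which change after the decoy receptor, and how alike both are.

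Mstn itself was measured in every class first. In experiment 2 its mean log2 value was 10.03 ± 0.16 (SD, n = 5) in controls and 7.25 ± 0.49 (SD, n = 8) in Mstn-null mice. In experiment 1 it was 7.35 ± 0.50 (SD, n = 3) in controls and 6.14 ± 0.48 (SD, n = 3) in Mstn-null mice, with the lowest control at 6.77 and the highest Mstn-null array at 6.69. Every Mstn-null array thus lay below every control array of its experiment. Over both experiments Mstn was 4.93-fold lower in Mstn-null muscle (log2 change -2.30 ± 0.23 SE, adjusted p = 3.54e-08). In experiment 1 alone the change was -1.21 (adjusted p = 0.114), and the change was larger in experiment 2 by a log2 difference of -1.58. After 1 dose of ActRIIB-Fc the log2 change of Mstn was 0.37 ± 0.25 SE (adjusted p = 0.593), and after 4 doses it was 0.38 ± 0.25 SE (adjusted p = 0.509). Which part of the gene the probes of this row cover is not given in the sources used here.

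**Figure D1:**
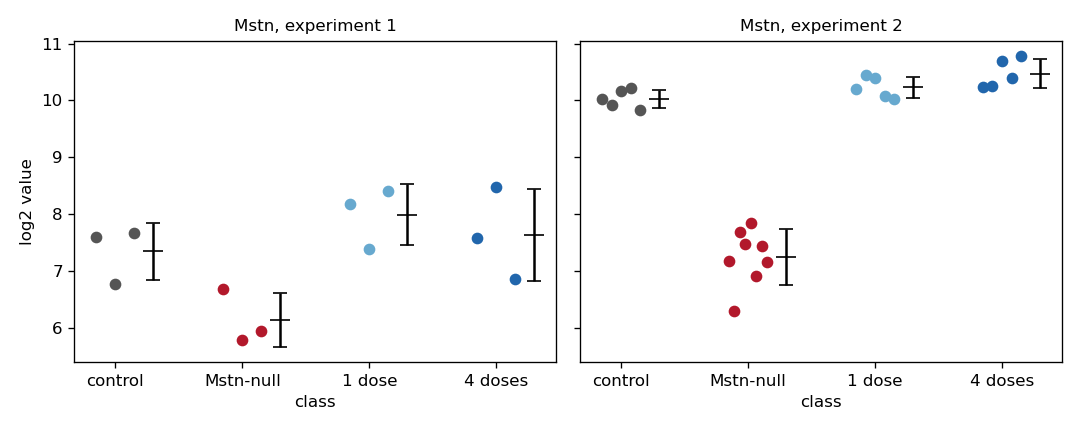
Log2 value of Mstn (vertical axis) on each array by class (horizontal axis), with experiment 1 and experiment 2 in separate panels; points are arrays and bars show the mean ± SD. The Mstn-null arrays lie lowest in both panels, with means of 6.14 and 7.25 against 7.35 and 10.03 in controls.

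Mstn-null muscle had lower transcripts of slow-twitch fibres and of oxidative energy metabolism than control muscle. Of 14 measured genes of the slow contractile apparatus, 13 fell, among them the slow myosin light chain Myl2 (-3.03 ± 0.49 SE, adjusted p = 2.64e-05), the calsarcin Myoz2 (-2.55 ± 0.36 SE, adjusted p = 5.66e-06) and the calcium store protein Casq2 (-1.66 ± 0.24 SE, adjusted p = 6.05e-06). Of 60 genes of oxidative phosphorylation 53 fell and none rose, with Cox6c at -1.90, Ndufa5 at -1.58, Ndufb3 at -1.19 and Uqcrfs1 at -1.10. All 22 genes of fatty acid uptake and oxidation fell, with the lipoprotein lipase gene Lpl at -1.35 and the acyl-CoA dehydrogenase genes Acadl at -1.22 and Acadm at -0.97. All 19 genes of the tricarboxylic acid cycle fell, led by the isocitrate dehydrogenase gene Idh2 at -1.26 and the pyruvate dehydrogenase gene Pdha1 at -1.07.

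The median log2 change was -2.01 for the slow fibre list (camera adjusted p = 3.49e-13), -0.58 for oxidative phosphorylation (2.57e-28), -0.89 for fatty acid genes (2e-21) and -0.54 for the tricarboxylic acid cycle (3.34e-15). For each of these 4 lists the result was adjusted p = 0.117 with an estimated correlation. Adjusted over the list alone, 13 slow fibre genes, 54 oxidative phosphorylation genes, 22 fatty acid genes and 19 tricarboxylic acid cycle genes fell.

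Genes of muscle atrophy, autophagy and FoxO signalling were also lower in Mstn-null muscle, with 15 of 27 lower and none higher (adjusted over the list alone, 17 lower and 1 higher). Examples were the mitophagy receptor gene Bnip3 (-0.84), the forkhead factor gene Foxo4 (-0.76), the autophagy gene Gabarapl1 (-0.67) and Nfe2l1 (-0.59), a regulator of proteasome genes. The list's median was -0.31 (camera adjusted p = 2.44e-07, adjusted p = 0.117 with an estimated correlation). It was -0.12 with each array's range of values as a covariate (camera adjusted p = 0.000958, adjusted p = 0.242 with an estimated correlation). The list was bright on average, at 9.49 on control replicate 1 of experiment 2, whose upper quartile was 7.59. With genes sorted by mean level into 10 bins, 869 of the 1994 brightest fell (median -0.19). Whether the list fell more than other genes of its level was not tested. Endothelial markers fell in 8 of 18 cases, with Egfl7 at -0.68 and Pecam1 at -0.59, and none rose (list median -0.22, camera adjusted p = 0.00071, adjusted p = 0.467 with an estimated correlation). Adjusted over the list alone, 8 endothelial markers fell. With each array's range of values as a covariate, the endothelial median was 0.01 (adjusted p = 0.303). Tendon markers fell in 6 of 13 cases, with Tnmd at -0.94 and Cpxm2 at -0.53 (list median -0.32, camera adjusted p = 0.000713, adjusted p = 0.314 with an estimated correlation). Adjusted over the list alone, 6 tendon markers fell and 1 rose.

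Of 51 cytoplasmic ribosomal protein genes 20 fell and 2 rose in Mstn-null muscle, the same counts as when adjusted over the list alone. The list's median of -0.16 (camera adjusted p = 5.42e-06, adjusted p = 0.652 with an estimated correlation) turned to 0.07 after quantile normalization. This list was bright too, at 10.12 on control replicate 1 of experiment 2, and was not tested against genes of its level. Macrophage and myeloid markers rose in 10 of 22 cases, 11 when adjusted over the list alone, with Laptm5 at 0.66 and S100a9 at 0.27. The list's median was 0.24 (camera adjusted p = 0.0252, adjusted p = 0.768 with an estimated correlation). That call was lost without control replicate 3 of experiment 2, with a median of 0.20 and adjusted p = 0.0935, and without Mstn-null replicate 5 of experiment 2, with 0.21 and adjusted p = 0.0746. In experiment 1 alone the median was -0.11 (adjusted p = 0.756). Without control replicate 3 of experiment 2, 4 of the 22 markers passed, and S100a9 did not pass after quantile normalization (0.13, adjusted p = 0.148) or with arrays centred on their medians (0.18, adjusted p = 0.0589).

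The largest falls outside these lists were those of Hmgn5, a nucleosome-binding protein gene (-3.30 ± 0.41 SE, adjusted p = 6.23e-07), Nexn, which encodes an actin-binding protein of the Z-disc (-2.62 ± 0.42 SE, adjusted p = 2.3e-05), and the leiomodin gene Lmod2 (-2.17 ± 0.23 SE, adjusted p = 6.04e-08). The largest rises were smaller. They included Ripor2 (1.22 ± 0.11 SE, adjusted p = 3.57e-09), the integrin gene Itga4 (1.22 ± 0.15 SE, adjusted p = 4.43e-07), Tnfaip2 (1.06 ± 0.17 SE, adjusted p = 2.59e-05), Naaladl2 (0.98), the insulin receptor substrate gene Irs1 (0.95), the muscle methyltransferase gene Mettl21e (0.95), the glycolytic regulator gene Pfkfb3 (0.94), Sox4 (0.93) and the nicotinamide riboside kinase gene Nmrk2 (0.92). Usp17ld rose by 1.25, but it belongs to a family of near-identical copies, so its own value is uncertain. In experiment 2 alone Mettl21e stood at 0.53.

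Of 19938 genes tested, 8337 passed an adjusted p of 0.05 between Mstn-null and control muscle, 5062 higher and 3275 lower. A change of at least 2-fold was found for 236 of them, 4 higher and 232 lower. With each array centred on its median, 1905 were higher and 4189 lower, so the share of higher calls went from 60.7% to 31.3%. The Mstn-null arrays had a narrower range of values than controls, with an interquartile range lower by a log2 difference of -0.26 ± 0.06 SE (exact permutation p = 0.000117, two-sided). With genes sorted by mean level into 10 bins of equal size, the median change was 0.17 in bins 4 and 5 and -0.19 in bin 10, the brightest. With each array's interquartile range as a covariate, 596 genes passed. Of the 54 genes that the naming rule chose in Mstn-null muscle, 30 still passed and 24 did not. Among the 24 were Myl2 (-1.81, adjusted p = 0.0656), Nexn (-1.45, adjusted p = 0.0712), Pecam1 (-0.21, adjusted p = 0.32), Gabarapl1 (-0.37, adjusted p = 0.0856), Foxo4 (-0.41, adjusted p = 0.107), Tnmd (-0.58, adjusted p = 0.0541), Cpxm2 (-0.32, adjusted p = 0.152), S100a9 (0.115, adjusted p = 0.505), Pfkfb3 (1.05, adjusted p = 0.052) and Nmrk2 (0.85, adjusted p = 0.0608). The slow fibre genes Tnnc1 (-1.64, adjusted p = 0.127), Myl3 (-1.345, adjusted p = 0.148), Myh7 (-1.295, adjusted p = 0.19) and Tpm3 (-1.22, adjusted p = 0.0955) were also among them. Myoz2 (-1.41, adjusted p = 0.0304) and Casq2 (-0.87, adjusted p = 0.033) still passed.

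A single dose of ActRIIB-Fc lowered Mss51, a gene for a mitochondrial protein of skeletal muscle, more than any other gene, 5.67-fold against control (log2 change -2.50 ± 0.20 SE, adjusted p = 1.44e-10). The ubiquitin ligase genes Fbxo32 (-1.02 ± 0.14 SE, adjusted p = 3.02e-05) and Trim63 (-0.93 ± 0.16 SE, adjusted p = 0.000609), both known from muscle atrophy, fell too. Further falls were those of the methyltransferase gene Inmt (-1.44 ± 0.23 SE, adjusted p = 0.000216), the glutathione-degrading enzyme gene Chac1 (-1.40 ± 0.23 SE, adjusted p = 0.000422), Tbc1d1, a regulator of glucose uptake (-1.22), the metalloproteinase inhibitor gene Timp4 (-1.20), Klhl38 (-1.18), Asb15 (-1.15) and the neuronal nitric oxide synthase gene Nos1 (-1.01). Odf3l2 fell as well (-1.34, adjusted p = 0.0216), but lost its call without any 1 of 5 arrays. Tnfaip2 rose most (1.52 ± 0.18 SE, adjusted p = 2.65e-06), followed among the rises that held without any 1 array by Rftn1 (0.74), the MEF2 coactivator gene Mamstr (0.74) and Tspan9 (0.73).

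The other 6 of the 10 largest rises after 1 dose lost their call without 4 to 8 of the arrays, each left out alone. Thus without control replicate 5 of experiment 2, Irs1 went from 0.79 to 0.69 (adjusted p = 0.0706), Nmrk2 from 0.87 to 0.79 (adjusted p = 0.0824) and Dusp10 from 0.80 to 0.70 (adjusted p = 0.106).

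The list of atrophy, autophagy and FoxO genes was lower after 1 dose, with a median of -0.21 (camera adjusted p = 5.4e-15, adjusted p = 0.0225 with an estimated correlation). Of its 27 genes 3 fell and none rose, and adjusted over the list alone 10 fell. With 1 array left out 2 to 5 passed, the most without control replicate 2 of experiment 1. The remaining fall of the 3, that of the forkhead factor gene Foxo1 (-0.88, adjusted p = 0.0267), was not past the threshold after quantile normalization (-0.82, adjusted p = 0.064) or without any 1 of 7 arrays. These were 1-dose replicates 1 and 3 of experiment 1 (adjusted p = 0.0759 and 0.067) and, in experiment 2, control replicates 3, 4 and 5 (0.0557, 0.0576 and 0.0732) and 1-dose replicates 1 and 2 (0.0705 and 0.0557). None of the 14 slow fibre genes passed after 1 dose, over all genes or adjusted over the list alone, with Myh7 at -1.11 (adjusted p = 0.36), although the list's median of -0.75 passed camera (adjusted p = 3.04e-05, adjusted p = 0.773 with an estimated correlation). None of the 22 macrophage and myeloid markers passed either, with Csf1r at 0.46 (adjusted p = 0.11), while adjusted over the list alone 9 rose (list median 0.23, camera adjusted p = 2.06e-06, adjusted p = 0.552 with an estimated correlation).

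The lists of oxidative phosphorylation, fatty acid genes, the tricarboxylic acid cycle and the cell cycle also passed camera after 1 dose, at medians of -0.10, -0.14, -0.09 and 0.08 (adjusted p = 3.04e-05, 5.26e-05, 0.00382 and 0.00386). No gene of these 4 lists passed over all genes. Adjusted over the list alone, 1 fatty acid gene fell and 1 cell cycle gene rose. With an estimated correlation each of the 3 metabolic lists had adjusted p = 0.773, and the cell cycle list had adjusted p = 0.322 with an estimated correlation. After quantile normalization the oxidative phosphorylation, tricarboxylic acid cycle and cell cycle lists no longer passed (adjusted p = 0.13, 0.241 and 0.112), nor did the 3 metabolic lists with the array range as a covariate (0.289 for oxidative phosphorylation, 0.202 for fatty acid genes, 0.595 for the tricarboxylic acid cycle).

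In all, 222 genes passed after 1 dose, 108 higher and 114 lower, and with each array centred on its median 59 were higher and 145 lower (28.9% higher against 48.6%). The count was 147 without control replicate 4 or without control replicate 5 of experiment 2.

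After 4 doses of ActRIIB-Fc, transcripts of dividing cells and of macrophages were higher and slow fibre transcripts lower than in control muscle. Of 29 cell cycle genes 17 rose and none fell, among them the cyclin D1 gene Ccnd1 (1.05 ± 0.11 SE, adjusted p = 3.64e-08), the proliferation marker Mki67 (0.98 ± 0.09 SE, adjusted p = 7.9e-09), the topoisomerase gene Top2a (0.95 ± 0.11 SE, adjusted p = 3.84e-07) and the cyclin A2 gene Ccna2 (0.94 ± 0.10 SE, adjusted p = 2.12e-07). Of 22 macrophage and myeloid markers 12 rose and none fell, with Cd68 at 0.68, Laptm5 at 0.67, Lcp1 at 0.54 and Fcgr3 at 0.48. The growth factor gene Igf2 rose 2.94-fold, more than any other named gene (1.55 ± 0.10 SE, adjusted p = 2.84e-13), and Mss51 fell most, by 2.31 on the log2 scale (SE 0.20, adjusted p = 7.88e-10).

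The cell cycle list had a median change of 0.25 after 4 doses (camera adjusted p = 4.06e-22, adjusted p = 1.11e-06 with an estimated correlation), and adjusted over the list alone 21 of its genes rose. The macrophage and myeloid list had a median of 0.54 (camera adjusted p = 2.45e-16, adjusted p = 0.0454 with an estimated correlation), and adjusted over the list alone 18 rose. Without control replicate 3 of experiment 2, 7 of the 22 markers passed. In experiment 1 the 4-dose change of Fcgr3 was 0.09, and in experiment 2 it was 0.72.

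**Figure D2:**
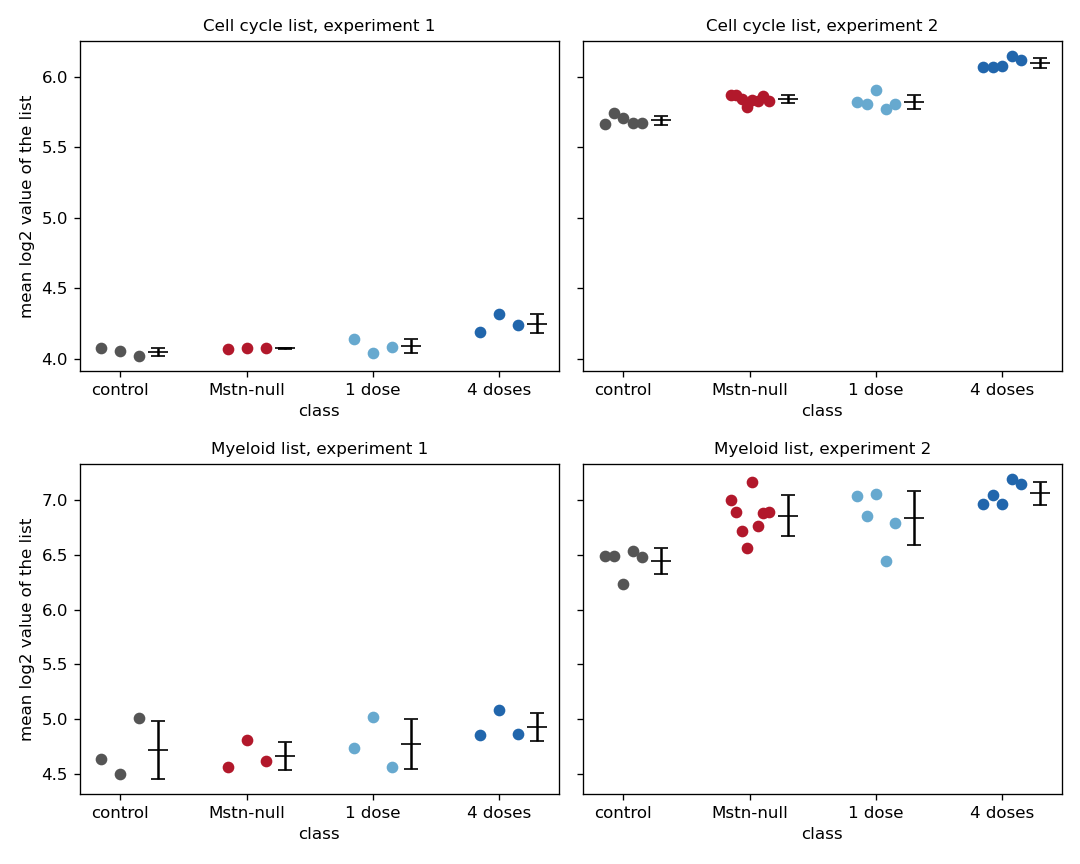
Mean log2 value of the cell cycle list and of the macrophage and myeloid list (vertical axes) on each array by class (horizontal axis), with experiments in separate panels; points are arrays and bars show the mean ± SD. Over both experiments the median gene of the cell cycle list changed by 0.25 and that of the macrophage and myeloid list by 0.54 after 4 doses.

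Of 14 slow fibre genes 9 fell after 4 doses and none rose, 10 when adjusted over the list alone, and 8 of the 10 largest falls were in this list. The slow troponin T gene Tnnt1 fell by 1.5 on the log2 scale (SE 0.34, adjusted p = 0.00753), the slow myosin heavy chain gene Myh7 by 2.00 (SE 0.50, adjusted p = 0.0171) and the calcium pump gene Atp2a2 by 1.39 (SE 0.35, adjusted p = 0.0167). The list's median was -1.41 (camera adjusted p = 1.37e-11, adjusted p = 0.143 with an estimated correlation). These calls depended on single arrays: without 4-dose replicate 3 of experiment 2 only 1 of the 9 genes, Tnnt1, still passed, with Myh7 at -1.81 (adjusted p = 0.0515), Atp2a2 at -1.26 (adjusted p = 0.0501), Tnnc1 at -1.86 (adjusted p = 0.0772) and Myl3 at -1.545 (adjusted p = 0.0982). Only 3 passed without 4-dose replicate 1 of experiment 2 and without control replicate 3 of experiment 1, each left out alone. Tnnt1 was the only gene that passed whichever array was left out. In experiment 2 the mean of the slow fibre list was 8.04 and 8.26 on 4-dose replicates 1 and 3. The other 4-dose arrays lay between 9.49 and 9.59, controls between 9.82 and 10.42, and 1-dose replicate 4 at 8.15. Replicate 3 after 4 doses was a narrow-range array in both experiments (interquartile range 2.22 and 2.26), while replicate 1 of experiment 2 had 2.70.

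Extracellular matrix genes rose in 9 of 32 cases after 4 doses, 21 when adjusted over the list alone, and none fell. The number of matrix genes past the threshold was 14 without control replicate 3 of experiment 1. The collagen genes Col3a1 (0.74), Col14a1 (0.62), Col6a2 (0.59) and Col15a1 (0.59) were among the 9 (list median 0.35, camera adjusted p = 3.91e-12, adjusted p = 0.185 with an estimated correlation). Of the 27 atrophy, autophagy and FoxO genes 4 fell, namely Trim63 (-0.87), Fbxo32 (-0.76), Gabarapl1 (-0.51) and the glucocorticoid-responsive factor gene Klf15 (-0.45), and none rose. Adjusted over the list alone 9 fell, and the list's median was -0.25 (camera adjusted p = 2.94e-08, adjusted p = 0.0999 with an estimated correlation). Other genes with large changes were the macrophage complement receptor gene Vsig4 (1.39 ± 0.20 SE, adjusted p = 2.69e-05), the protease inhibitor gene Serpinb1a (1.10), the imprinted gene Mest (1.09), the creatine synthesis gene Gamt (1.05), Tnfaip2 (1.03), the death receptor ligand gene Tnfsf10 (1.0) and Inmt (-1.91).

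Few genes of the metabolic lists passed after 4 doses. Of the fatty acid genes 1 of 22 fell, Lpl at -0.86 (5 when adjusted over the list alone; list median -0.32, camera adjusted p = 7.19e-09, adjusted p = 0.217 with an estimated correlation). Without control replicate 2 of experiment 1, 3 fatty acid genes passed. Of the tricarboxylic acid cycle genes 1 of 19 fell, Idh2 at -0.66, also when adjusted over the list alone (list median -0.12, camera adjusted p = 0.000592, adjusted p = 0.461 with an estimated correlation). No oxidative phosphorylation gene passed, over all 60 or adjusted over the list alone (list median -0.12, camera adjusted p = 1.76e-06, adjusted p = 0.466 with an estimated correlation). With the array range as a covariate the last 2 lists no longer passed (adjusted p = 0.222 for the tricarboxylic acid cycle and 0.0782 for oxidative phosphorylation).

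In all, 626 genes passed after 4 doses, 380 higher and 246 lower, with 26 changed at least 2-fold. With each array centred on its median, 232 were higher and 317 lower, a share of 42.3% higher against 60.7%.

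Muscle after 4 doses and after 1 dose was also compared directly. Only the number of doses was used here. Effects of repeated dosing, of the length of treatment and of the time since a dose therefore cannot be told apart. Igf2 was higher after 4 doses than after 1 dose (1.44 ± 0.10 SE, adjusted p = 3.36e-12), as were the imprinted genes Mest (0.98 ± 0.11 SE, adjusted p = 1.79e-06) and Cdkn1c (0.87 ± 0.07 SE, adjusted p = 6.52e-10), the latter a cell cycle inhibitor gene. Cell cycle genes were higher in 7 of 29 cases and lower in none, led by Ccnd1 (0.83), Mki67 (0.72), Ccna2 (0.70) and Top2a (0.64). The list's median difference was 0.16 (camera adjusted p = 1.66e-22, adjusted p = 9.35e-07 with an estimated correlation), and adjusted over the list alone 11 were higher. Extracellular matrix genes and macrophage and myeloid markers had median differences of 0.23 and 0.17 (camera adjusted p = 7.94e-13 and 1.03e-06, for both adjusted p = 0.282 with an estimated correlation), with no gene past the threshold over all genes and 10 and 5 higher when adjusted over the list alone.

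In this comparison 64 genes passed, 55 higher and 9 lower after 4 doses. In experiment 1 alone the balance was the reverse, with 11 higher and 37 lower of 48 genes, 5 of them shared with the 64, while in experiment 2 alone 39 were higher and 3 lower of 42. In experiment 1 alone Mest (0.67, adjusted p = 0.164) and Ccnd1 (0.65, adjusted p = 0.117) did not pass. H2-Aa, a gene of antigen presentation, was higher by 0.79 (adjusted p = 0.0163), but not past the threshold without 4-dose replicate 4 of experiment 2 (0.74, adjusted p = 0.0554) or 1-dose replicate 3 of experiment 1 (0.75, adjusted p = 0.0542). The 5 largest falls, Myom3, Klf10, Rpia, Gpt and Wnt5a, lay between -0.65 and -0.38, and each lost its call without at least 6 of the arrays left out in turn, as Myom3 did without 4-dose replicate 1 of experiment 2 (-0.57, adjusted p = 0.0838). The count was 27 without 1-dose replicate 3 of experiment 1, 32 without 4-dose replicate 4 of experiment 2, 38 without 1-dose replicate 1 of experiment 2 and 39 without 4-dose replicate 2 of experiment 1. It was 40 without 4-dose replicate 5 and 41 without 4-dose replicate 1 of experiment 2.

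Treated and Mstn-null muscle were also compared with each other, which leaves the controls out of the difference. Mss51 was lower after treatment than in Mstn-null muscle, by a log2 difference of -2.22 ± 0.18 SE after 1 dose (adjusted p = 6.54e-10) and -2.02 ± 0.18 SE after 4 doses (adjusted p = 2.33e-09). In Mstn-null muscle it differed from control by -0.29 (adjusted p = 0.2). Mstn-null replicate 4 of experiment 2 stood at 10.81 for Mss51, the others of its group between 8.77 and 9.58. That array raised the Mstn-null mean, so a fall of Mss51 in Mstn-null muscle is not excluded. Mettl21e was lower after 1 dose (-1.64) and 4 doses (-1.43), as was the muscle structural gene Igfn1 (-1.17 and -1.23). Mstn was higher in both, by 2.67 and 2.69, and so were Hmgn5 (2.48 and 1.91), Nexn (2.13 and 1.65) and Casq2 (1.87 and 1.70). After 4 doses the cartilage and tendon matrix gene Aspn was higher by 1.82, and the lipid synthesis genes Fasn and Acaca were lower (-1.5 and -1.23). After 1 dose Arrdc3 (-1.17) and Naaladl2 (-1.14) were lower.

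Against Mstn-null muscle, oxidative phosphorylation genes were higher in 48 of 60 cases after 1 dose and in 43 after 4 doses, and none was lower (52 and 51 when adjusted over the list alone). Cox6c differed by 1.69 and 1.48, and Uqcrfs1 by 0.92 and 0.83. The list's median differences were 0.46 and 0.46 (camera adjusted p = 2.59e-29 and 1.09e-25, adjusted p = 0.176 and adjusted p = 0.191 with an estimated correlation). Fatty acid genes were higher in 20 of 22 cases after 1 dose and in all 22 after 4 doses, with 22 in both when adjusted over the list alone (medians 0.67 and 0.58, camera adjusted p = 5.03e-22 and 1.25e-16, adjusted p = 0.146 and adjusted p = 0.177 with an estimated correlation). Tricarboxylic acid cycle genes were higher in 16 of 19 cases in both, 17 when adjusted over the list alone (medians 0.45 and 0.46, camera adjusted p = 8.5e-16 and 7.97e-14, adjusted p = 0.174 and adjusted p = 0.177 with an estimated correlation). Slow fibre genes were higher in 13 of 14 cases after 1 dose and in 5 after 4 doses, with the same counts when adjusted over the list alone (medians 1.39 and 0.77, camera adjusted p = 5.6e-11 and 1.66e-05, adjusted p = 0.207 and adjusted p = 0.38 with an estimated correlation). Cell cycle genes were higher after 4 doses than in Mstn-null muscle in 12 of 29 cases and lower in 1, with 14 higher and 1 lower when adjusted over the list alone (median 0.14, camera adjusted p = 1.49e-08, adjusted p = 0.00394 with an estimated correlation).

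In all, 3354 genes differed between 1 dose and Mstn-null muscle, 2178 higher and 1176 lower after treatment, and 4019 between 4 doses and Mstn-null muscle, 2275 higher and 1744 lower. In experiment 1 alone 400 genes passed for 1 dose but only 3 for 4 doses (941 at an unadjusted p under 0.05). In experiment 2 alone the counts were 2611 and 5716, so the 4-dose count rested on experiment 2. The higher share went from 64.9% to 77.9% for 1 dose and from 56.6% to 74% for 4 doses with each array centred on its median, and for 1 dose to 52.5% after quantile normalization. With the array range as a covariate the counts were 501 and 394, and Hmgn5, Fasn and Acaca were then not past the threshold in the 4-dose comparison, nor Nexn in either. Without 4-dose replicate 5 of experiment 2, 14 fatty acid and 3 slow fibre genes passed in the 4-dose comparison, and without 1-dose replicate 3 of experiment 2, 8 slow fibre genes passed in the 1-dose comparison. The 4-dose count was 6494 without 4-dose replicate 3 of experiment 1, 2338 without 4-dose replicate 1 of experiment 2 and 2282 without 4-dose replicate 5 of experiment 2.

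The change profiles of treated and Mstn-null muscle were set side by side across all genes, which are not independent replicates. The correlation of log2 changes was 0.609 between Mstn-null muscle and 4 doses, 0.615 between Mstn-null muscle and 1 dose, and 0.707 between both doses. Unchanged groups simulated against the same controls gave mean correlations of 0.536, 0.536 and 0.5. Their genes varied independently, unlike those of real arrays. The simulation therefore does not show how far such correlations stray without any change. The covariances were 0.0308, 0.0270 and 0.0169 against simulated covariances of 0.00506, 0.00505 and 0.00506. With the controls divided between the comparisons the correlations were 0.506, 0.492 and 0.498, and the covariances 0.0272, 0.0233 and 0.0137. With no array shared, taking the first comparison from experiment 1 and the second from experiment 2, they were 0.175, 0.258 and 0.296, and in the reverse order 0.466, 0.093 and 0.33.

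Of the 380 genes that rose after 4 doses, 205 also rose in Mstn-null muscle (96.5 for independent lists), and of the 246 that fell, 192 also fell there (40.4 for independent lists), while 4 moved in opposite directions. Of the 108 that rose after 1 dose, 81 also rose in Mstn-null muscle (27.4 for independent lists), and of the 114 that fell, 78 also fell there (18.7), with 1 in opposite directions. Both doses shared 45 rises (2.1 for independent lists) and 67 falls (1.4), with 0 in opposite directions by limma. The independent values leave out the controls that these comparisons share.

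The follow-up experiment was set against the first one, each fitted alone. Of 477 genes past the threshold in Mstn-null muscle in experiment 1, 445 had the same sign in experiment 2 (93.3%) and 350 of them also passed there, adjusted over those genes. After 4 doses the corresponding values were 53, 51 (96.2%) and 26, and after 1 dose all 5 genes had the same sign and passed. Most calls of experiment 1 were falls, 396 of the 477 in Mstn-null muscle (17% higher, against 60.7% over both experiments), 34 of the 53 after 4 doses (35.8% higher, against 60.7%) and 4 of the 5 after 1 dose. In experiment 2 rises were more frequent, with 62.3% higher in Mstn-null muscle, 66.7% after 4 doses and 57.7% after 1 dose. In the reverse direction, 8755 genes passed in Mstn-null muscle in experiment 2, of which 6180 had the same sign in experiment 1 (70.6%) and 510 passed. After 1 dose they were 246, 200 (81.3%) and 56, and after 4 doses 523, 424 (81.1%) and 102.

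The interaction test found 334 genes whose Mstn-null effect differed between the experiments, 270 with a more positive and 64 with a more negative change in experiment 2. That count depended on single arrays. In experiment 1 it was 0 by limma without Mstn-null replicate 1, 10 without control replicate 2, and it rose to 418 more positive and 108 more negative changes without 1-dose replicate 2. In experiment 2 it was 200, 112 and 75 without control replicates 3, 4 and 5, and 561 and 1159 without Mstn-null replicates 3 and 5. With all arrays it was 0 at an adjusted p of 0.01, 31 with arrays centred on their medians and 39 after quantile normalization, and 4403 genes had an unadjusted p under 0.05. For 1 dose no gene differed between experiments by limma, with 1022 at an unadjusted p under 0.05, while a fit with array weights, whose estimation did not converge, gave 272, and 1612 for 4 doses. For 4 doses 1 gene did in the main fit and 0 by limma without the 6 arrays of narrowest range (1766 at an unadjusted p under 0.05). It was Chac1, which was chosen after its values were seen. Its 4-dose change was 0.64 in experiment 1 and -1.56 in experiment 2, a difference of -2.19 ± 0.32 SE (adjusted p = 0.00134).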

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

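Of the tests in this part, those on the array range and on the share of muscle RNA were chosen after the result was seen, as was the reshuffling matched on expression of genes near Mstn. The other tests were set before.

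The many genes called between Mstn-null and control muscle went with a narrower range of values on the Mstn-null arrays. After quantile normalization, which gives all arrays 1 range, 53.9% of the calls stayed past the threshold with the same sign, and with the range as a covariate 6.3% did. The median size of these genes' changes went from 0.30 (median SE 0.09) to 0.23 (0.08) and to 0.13 (0.10), with 99.6% and 88.5% keeping their sign, so under the covariate calls ended mostly because the changes shrank. Class and range overlap (variance inflation 1.75), so for the whole count a technical difference in range and a biological change of many transcripts cannot be told apart. For the oxidative phosphorylation and slow fibre lists the values argue against the range as the whole cause: its slope in the 24 other arrays predicts -0.105 for oxidative phosphorylation (95% interval -0.196 to -0.015) against an observed mean of -0.62 ± 0.10 SE, and -0.528 for slow fibre genes (-1.092 to 0.035) against -1.97 ± 0.34 SE, which leaves a lower slow and oxidative program in muscle without myostatin as a hypothesis.

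After 4 doses, higher macrophage and cell cycle lists may come from cells other than muscle fibres. A lower share of muscle RNA would raise the markers of every other cell type alike, but the myeloid list rose by 0.47 ± 0.10 SE while the mean of the endothelial, Schwann and smooth muscle lists changed by -0.01 ± 0.04 SE (exact permutation p = 0.00159 for the difference of 0.47, 8 against 8 arrays). Extracellular matrix genes (0.31 ± 0.10 SE), fibro-adipogenic progenitor markers (0.19 ± 0.09 SE) and satellite cell genes (0.11 ± 0.024 SE) also had positive mean changes. Adipocyte (-0.362 ± 0.235 SE), tendon (-0.19 ± 0.08 SE) and smooth muscle (-0.081 ± 0.042 SE) lists had negative ones. Over all 10 other fixed lists not specific to fibres the mean changed by 0.02 ± 0.05 SE (exact permutation p = 0.00119 for the difference of 0.45). That mean sets rises against falls. The myeloid list exceeded the matrix list by 0.155 ± 0.07 SE (exact permutation p = 0.0171). The lists did not rise alike, which argues against a lower muscle share as the whole cause. A part from it, more myeloid cells or more myeloid transcripts per cell stay open. Dividing myeloid cells as a source of the cell cycle list cannot be told apart from other dividing cells, since across all 35 arrays within groups the list means correlated weakly (Pearson r = 0.314, permutation p = 0.117; Spearman rho = 0.252, permutation p = 0.189; 0.152 without the 2 arrays farthest from the median). The lists share 0 genes, and r was -0.116 over the 12 arrays of experiment 1 and 0.561 over the 23 of experiment 2.

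Some calls in Mstn-null muscle may come from the strain in which the deletion was made rather than from the missing gene. Genes changed by at least 0.5 in Mstn-null muscle and different there from both treated classes, 53 higher and 981 lower, were placed among 19854 genes in chromosomal order: 17 of the 100 genes nearest to Mstn were among them, more than in 99.1% of windows of that size (median 5, 95th percentile 11). With expression matched, reshuffles gave a median of 6 and a 95th percentile of 10 (permutation p = 2e-04). Over the whole order 98 pairs of such genes were neighbours against a median of 64 in reshuffles (95th percentile 77, permutation p = 2e-04), a ratio of 1.53, compared with 1.23 for as many genes after 4 doses. Segments of another strain could give both counts, but neighbours can also share regulation, and no genotype was analysed here. The change of any gene near Mstn thus has this as an open explanation. Examples are Hibch (-0.97), Mettl21e (0.95), Ankrd44 (0.65) and Ndufb3 (-1.19), the last also named above for oxidative phosphorylation. Hibch and Ankrd44 were named after their values were seen.

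Other splits of the same arrays within experiments were fitted, 100 per comparison with the real one included. Only 1 split, the real one, gave as many genes in each of the 6 comparisons. This makes chance unlikely there but does not exclude it, since 100 splits cannot show a share below 1 in 100. The real counts and the highest of the other splits were 8337 and 4464 for Mstn-null against control, 222 and 3 for 1 dose, 626 and 48 for 4 doses, 64 and 35 for 4 doses against 1 dose, 4019 and 2483 for 4 doses against Mstn-null, and 3354 and 281 for 1 dose against Mstn-null. For the tests between experiments, 4 of 100 reassignments gave as many genes as the 334 for Mstn-null, the highest of the others giving 1615, and 3 of 100 gave as many as the 1 for 4 doses, the highest of the others giving 834. Reassignments that call several times the real count point to a structure of the arrays, whose source was not tested. For 1 dose limma found 0 genes (1022 at an unadjusted p under 0.05), which all 100 reassignments reach by construction (highest 1), so they say nothing about chance.

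Differences between the experiments under the same contrast stood out for 334 genes in Mstn-null muscle and 1 gene, Chac1, after 4 doses. Among named genes the Mstn-null change was more negative in experiment 2 for Mstn (difference -1.575) and the tendon gene Kera (-1.315), and more positive for the myeloid gene Itgam (0.651). Among 13767 rows without a single gene symbol, which the comparisons left out, 3292 passed the threshold for Mstn-null against control, 35 for 1 dose and 181 for 4 doses.

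A single array stood far from the rest of its group in 18 of 344 groups tested, where chance gives about 1 in 20. Only groups of experiment 2 were tested, since those of experiment 1 held 3 arrays each. For list means in experiment 2, control replicate 5 had 9.87 for ribosomal proteins (others 10.05 to 10.12), control replicate 3 had 8.44 for fibro-adipogenic progenitors (others 8.61 to 8.66) and 6.24 for myeloid markers (others 6.48 to 6.53), and control replicate 4 had 7.72 for TGF-beta signalling (others 7.63 to 7.65). Single-dose replicates 2, 3 and 4 had 7.98 for smooth muscle (others 8.15 to 8.19), 5.17 for lymphocytes (others 5.40 to 5.44) and 6.93 for ATF4 genes (others 6.83 to 6.85). Replicate 3 after 4 doses had 7.64 for denervation genes (others 7.56 to 7.58), and Mstn-null replicates 1 and 5 had 8.56 for immediate early genes (others 7.46 to 7.86) and 6.72 for interferon genes (others 6.21 to 6.44).

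For single genes in experiment 2, Mstn-null replicate 5 had 7.38 for Hmgn5 (others 3.73 to 5.25) and 8.88 for Inmt (others 6.77 to 7.67), and Mstn-null replicate 4 had 10.81 for Mss51 (others 8.77 to 9.58). After 4 doses, replicate 1 had 8.51 for Chac1 (others 7.62 to 7.77) and 8.28 for Tnfsf10 (others 7.01 to 7.38), and replicate 3 had 5.81 for Vsig4 (others 6.54 to 6.73). After 1 dose, replicate 3 had 6.57 for Vsig4 (others 4.75 to 5.23) and replicate 4 had 6.37 for Ccnd1 (others 6.76 to 6.91).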

How the results depend on the processing

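The array range as a covariate and the removal of 6 narrow-range arrays were added after the data were seen, and all other settings were planned. The counts kept within 1.5 times of the main value with trend and robust settings, but depended on most other settings. Unless a cause is given, the cause was not tested.

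With no experiment term 0 genes passed in any of the 6 comparisons by limma (3 to 202 at an unadjusted p under 0.05), because the level difference between experiments then enters the spread. In experiment 1 alone, with fewer arrays, 477 genes passed for Mstn-null against control (81 higher, 396 lower), 5 for 1 dose (1 and 4), 53 for 4 doses (19 and 34), 48 for 4 doses against 1 dose (11 and 37), 3 for 4 doses against Mstn-null and 400 for 1 dose against Mstn-null, and in experiment 2 alone 42 for 4 doses against 1 dose. Fewer arrays alone need not account for the 3, since the 400 came from as many arrays. In experiment 1 the Mstn-null changes of Itgam (-0.088), Csf1r (-0.066) and Kera (0.062), of the extracellular matrix list (-0.17, past the threshold downward at adjusted p = 0.0129) and the myeloid list (-0.11, adjusted p = 0.756), the difference of Hk2 between 4 doses and Mstn-null (0.076), and that of the endothelial list (-0.014) between 4 doses and 1 dose turned sign, and for the tendon list (-0.001, main value -0.121) only camera's direction did.

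Centring on the median gave 31 and quantile normalization 39 genes for the Mstn-null effect between experiments. Quantile normalization turned the ribosomal list in Mstn-null (0.073) and, for 4 doses against Mstn-null, the atrophy (-0.028), ribosomal (-0.073) and glycolysis (-0.057) lists. Without the dimmest tertile 34 genes passed for 4 doses against 1 dose, and 594 (Mstn-null) and 6 (4 doses) for the effects between experiments. With every row tested these were 36 for 4 doses against 1 dose and 654 for Mstn-null between experiments. Array weights gave 1743 for 1 dose, 1543 for 4 doses, 437 for 4 doses against 1 dose, and 1501, 272 and 1612 for the effects of Mstn-null, 1 dose and 4 doses between experiments, where the estimation of the weights did not converge. A fit of only the classes compared gave 494 for 1 dose, 964 for 4 doses and 1707 for 4 doses against Mstn-null.

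By construction stricter thresholds gave fewer genes. At an adjusted p of 0.01 they were 4737, 108, 306, 18, 1420 and 1477 for Mstn-null, 1 dose, 4 doses, 4 doses against 1 dose, 4 doses against Mstn-null and 1 dose against Mstn-null, and 0 for Mstn-null between experiments (4403 at an unadjusted p under 0.05). With a change of at least 0.5 they were, in that order, 1523, 93, 228, 27, 1002 and 1025.

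With the array range as a covariate the counts were 596 for Mstn-null, 135 for 4 doses against 1 dose, 394 for 4 doses against Mstn-null and 501 for 1 dose against Mstn-null, and 874 (Mstn-null) and 10 (4 doses) between experiments, and Emcn turned to 0.023 in Mstn-null. Without the narrow-range arrays they were 5079 for Mstn-null, 448 for 1 dose, 204 for 4 doses against 1 dose and 1419 for 1 dose against Mstn-null, and 851 (Mstn-null) and 0 (4 doses, 1766 at an unadjusted p under 0.05) between experiments. The slow fibre list in Mstn-null stood at -1.16 with the covariate and -1.55 without those arrays, and oxidative phosphorylation at -0.34 and -0.36, all past the threshold by camera at the preset correlation but not with an estimated correlation (adjusted p = 0.122 and 0.129 for slow fibre, 0.186 and 0.0853 for oxidative phosphorylation).

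With the replicate number as a block 4982 genes passed for Mstn-null, 1212 for 4 doses against Mstn-null and 1244 for 1 dose against Mstn-null, and the other counts were 231, 654 and 59. The numbers do not pair the arrays, since deviations of same-numbered arrays correlated between -0.60 and 0.415, with a mean of -0.001 over 48 pairs.

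Leaving out each array in turn gave 6965 to 9187 genes for Mstn-null, 147 to 327 for 1 dose, 456 to 698 for 4 doses, 27 to 83 for 4 doses against 1 dose, 2282 to 6494 for 4 doses against Mstn-null, 2303 to 3960 for 1 dose against Mstn-null, and 0 to 1159, 0 to 0 and 1 to 4 for the effects of Mstn-null, 1 dose and 4 doses between experiments. Of 240 calls of named genes 35 were lost without at least 1 array, and of 70 list calls 13 were. Among results not called in the main fit, 21 of named genes and 9 of lists gained a call without at least 1 array. Interferon genes after 4 doses (main adjusted p = 0.0725) did so for 8 arrays, and in Mstn-null muscle glycolysis genes for 4 and lymphocyte markers for 3. With all arrays, fry in place of camera ended 36 list calls and added 8, and camera with an estimated correlation ended 65.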

Other observations

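In this part the array range as a covariate was chosen after the results were seen. The test of imprinted genes was prompted by results too, but set before its own result was seen. Several groups of genes outside the main themes also changed after 4 doses. Fast fibre contractile genes rose in 3 of 16 cases and fell in none, with the myosin light chain genes Myl1 at 0.34 and Mylpf at 0.28 (list median 0.07, camera adjusted p = 0.0108, adjusted p = 0.466 with an estimated correlation). After quantile normalization that list did not pass (adjusted p = 0.743). Satellite cell and myogenic genes rose in 3 of 21 cases and fell in 1, with the fusion gene Mymk at 0.48 and Vcam1 at 0.34 (list median 0.09, camera adjusted p = 0.0148, adjusted p = 0.0999 with an estimated correlation). Denervation and junction genes rose in 2 of 20 cases, with the cardiac actin gene Actc1 at 0.68 (list median 0.07, camera adjusted p = 0.0187, adjusted p = 0.185 with an estimated correlation), and progenitor markers in 2 of 11, with Smoc2 at 0.54 (list median 0.13, camera adjusted p = 0.0274, adjusted p = 0.447 with an estimated correlation). Without control replicate 2 of experiment 1 neither list passed (denervation 0.07, adjusted p = 0.0719; progenitors 0.09, adjusted p = 0.125). The progenitor list also did not pass without control replicate 3 (0.08, adjusted p = 0.0957) or 4-dose replicate 5 (0.10, adjusted p = 0.1) of experiment 2.

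The adipocyte list had a median of -0.37 after 4 doses with 0 of 14 genes past the threshold by limma (camera adjusted p = 0.000718, adjusted p = 0.447 with an estimated correlation). The tendon list stood at -0.15 with 0 of 13 (0.000592, adjusted p = 0.217 with an estimated correlation), the ribosomal list at -0.06 with 0 of 51 (0.00293, adjusted p = 0.565 with an estimated correlation) and the clock list at -0.09 with 1 of 16 (0.0148, adjusted p = 0.217 with an estimated correlation). After quantile normalization the ribosomal and clock lists did not pass (adjusted p = 0.356 and 0.131). Single arrays moved these small counts, and with 1 array left out as few as 2 satellite cell, 1 denervation, 1 progenitor and 0 clock genes passed by limma. Adjusted over the list alone, 5 fast fibre, 6 satellite cell, 2 denervation and 3 progenitor genes rose, 1 satellite cell and 2 clock genes fell, and no adipocyte, tendon or ribosomal gene passed.

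In the main fit the remaining lists did not pass camera in any comparison against control. Their medians in Mstn-null muscle, after 1 dose and after 4 doses were 0.11, -0.01 and 0.001 for the IGF, AKT and mTOR pathway, 0.11, -0.005 and -0.01 for TGF-beta and activin signalling, 0.18, 0.09 and 0.09 for BMP targets, -0.02, -0.01 and 0.01 for glycolysis and glycogen, 0.05, 0.08 and 0.05 for ATF4 and serine synthesis, and 0.08, 0.13 and 0.03 for polyamine metabolism. They were 0.13, 0.21 and 0.11 for immediate early genes, 0.04, -0.04 and 0.07 for interferon genes, 0.18, 0.08 and 0.05 for lymphocyte markers, 0.09, 0.02 and -0.06 for smooth muscle markers, 0.15, 0.05 and 0.02 for Schwann cell markers, 0.27, 0.01 and 0.08 for erythroid markers, and 0.04, -0.02 and -0.01 for the sex genes. In the main fit 13 cell cycle, 9 matrix and 14 IGF pathway genes passed over all genes in Mstn-null muscle, but none of these lists passed camera there. With the array range as a covariate, the cell cycle (0.11), extracellular matrix (0.18) and IGF pathway (0.17) lists passed in Mstn-null muscle (adjusted p = 0.000523, 0.000993 and 0.000523), but not with an estimated correlation in that fit (adjusted p = 0.122, 0.763 and 0.0728). In experiment 1 alone the matrix list passed downward (-0.17, adjusted p = 0.0129, adjusted p = 0.918 with an estimated correlation).

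For some lists that did not pass, median, mean and camera direction differed in sign. Against control these were adipocyte, ATF4, interferon, polyamine and smooth muscle genes in Mstn-null muscle, ATF4, ribosomal, fast fibre, progenitor, IGF pathway and TGF-beta genes after 1 dose, and ATF4, endothelial, glycolysis, immediate early, Schwann cell, sex and TGF-beta genes after 4 doses. Between 4 doses and 1 dose they were ATF4, BMP, clock, IGF pathway and polyamine genes, and between 4 doses and Mstn-null ATF4, BMP and TGF-beta genes. Between 1 dose and Mstn-null they were adipocyte, ATF4, BMP, cell cycle, clock, denervation, matrix, immediate early, interferon, myeloid and satellite cell genes.

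Igf2, Mest and Cdkn1c are imprinted growth genes, and all were higher after 4 doses than after 1 dose, so a wider rise of such genes was taken as a hypothesis and its test set before its result was seen. Of 17 measured genes among 19 other imprinted ones, 1 rose after 4 doses against control, Grb10 (0.48 ± 0.07 SE, adjusted p = 2.06e-05), and adjusted over the list alone 4 rose and 1 fell. The list was shifted upward by a median of 0.09 (camera p = 0.0229, p = 0.0385 with an estimated correlation), which is consistent with the hypothesis, but adjusted over the 4 comparisons tested it did not pass (adjusted p = 0.0692). Its camera p was 0.0346 after 1 dose (adjusted p = 0.0692), 0.598 in Mstn-null muscle and 0.584 between 4 doses and 1 dose. The other imprinted genes thus gave no sign of a further rise from 1 dose to 4 doses. In Mstn-null muscle Igf2 changed by 0.36 (adjusted p = 0.00317) and Cdkn1c by 0.002 (adjusted p = 0.985).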
